A study of Sinapis alba with 12 samples.

How the data were processed

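RNA was measured in 12 libraries of white mustard, 3 each of control leaves, cadmium leaves, control roots and cadmium roots, taken 45 days after planting. The libraries were grouped by their labels. Per the file headers, the deposited table gives for each of 87417 assembled transcripts a read count and an FPKM value per library, and the counts were used as deposited. FPKM is a unit that scales counts to transcript length and library size, and the FPKM values were used as deposited. Per the file headers, the authors also ran DESeq2 and marked transcripts at a p of 0.01 and a fold change of 1.5, and these marks were only compared with the calls made here. The assembly, the aligner and the counting tool are not given in the sources used here. The identifiers have the form of components of a de novo assembly and carry no genome positions, so a transcript here need not be a whole gene, and near-identical copies share reads.

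Total counts per library were between 13083458 and 16724809. In simulated data made from these libraries, with 200 changed genes per comparison, edgeR found 6%, 17.9% and 71.2% of genes changed 1.5-fold, 2-fold and 4-fold in the leaf, and 53.7%, 74.6% and 90.9% in the root. It found 3%, 22.4% and 78.8% for the difference between tissues and 9%, 46.3% and 89.4% for root against leaf, with 2, 12, 4 and 8 false calls. The list test, also tested on simulated data, found the changed list in each comparison and no false list. The simulated genes vary independently, with a spread set by their expression level alone, so the shares found need not hold for the real libraries. The simulation also does not measure false list calls among correlated genes. Other splits of the real libraries called 5 to 15 lists in the leaf and 1 to 7 in the root.

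The groups, comparisons, gene lists, rule for named genes and alternatives were written before the data were examined. The test planned then was limma on log2(FPKM + 1), because only FPKM values were expected. The table holds counts, so edgeR was used in its place and the planned test became an alternative. Genes were tested with edgeR 4.0.16 (TMM scaling, glmQLFit and glmQLFTest) where FPKM was at least 1 in at least 3 libraries of the comparison, and for the difference between tissues in at least 3 libraries of each tissue. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The comparisons were cadmium against control in the leaf and in the root, each fitted to its 6 libraries, root change minus leaf change in 1 fit of 12 libraries, and control root against control leaf. Standard errors of log2 fold changes were approximated as the fold change over the square root of the F statistic. An exact test of 3 against 3 libraries cannot give a p under 0.1, so none was used for single genes.

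Each transcript took its name from its Swiss-Prot match, present for 33423 transcripts, 27069 of them to Arabidopsis, or else from its nr match, present for 59625. Bare locus names counted as no name. Transcripts matched to oomycetes, fungi, algae or protists with under 2% of their counts per library in the leaf were classed as other organisms. Once this annotation had been seen, named genes and lists were limited to plant and unmatched transcripts, and the wider lists became an alternative. The 30 gene lists were built from symbols, loci and phrases, so a member can match by symbol alone. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, for lists of at least 5 tested members, with adjustment over the lists of a tissue.

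Named genes in leaf and root were the 10 largest rises and 10 largest falls among called genes with at least 5 FPKM in the higher group, a name, and no overlap between groups. Because 0 genes were called in the leaf, its genes were ranked by unadjusted p. The rule also named up to 2 called members per direction of each list with the highest FPKM, and PCS1, HMA3, HMA4, IRT1, NRAMP3, MT2A, GSH1 and APR2 whether or not they passed. For the other 2 comparisons it named 5 genes per direction. For the difference between tissues, no overlap meant that every cadmium minus control difference of log2(FPKM + 1) in the root lay on one side of every such difference in the leaf. The text gives part of the genes this rule named. Folds against a group without counts were computed against a floor of 3 counts over the group.

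The alternatives planned were limma on log2(FPKM + 0.1) and on log2(FPKM + 0.5), no filter, an FPKM of at least 5, median-ratio scaling, quantile normalization, no variance trend, the replicate number as a block, all 12 libraries in 1 fit, and each library left out in turn. Those added after the data were seen were DESeq2 1.42.0, plant transcripts only, lists with other organisms kept, and voom with weights. Limma on log2(FPKM + 1), planned as the main test, joined the alternatives when edgeR replaced it. Computations ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.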

Results

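RNA was sequenced from leaves and roots of white mustard (Sinapis alba), harvested 45 days after planting from control plants and from plants treated with cadmium, a toxic heavy metal. The 12 libraries formed 4 groups of 3, which were control leaf, cadmium leaf, control root and cadmium root. Mean total counts were 15467913 in control leaves, 15217409 in cadmium leaves, 14458761 in control roots and 14231246 in cadmium roots, and single libraries held between 13083458 and 16724809 counts. The deposited table lists 87417 assembled transcripts without genome positions, and each is called a gene here. All levels are mean FPKM ± SD over the 3 libraries of a group (n = 3). Fold changes come from the counts, and for some genes, such as TIFY10A, they differ from the ratio of the FPKM values. Nothing in the labels says that the libraries of a group came from separate plants, so p-values measure the spread between these samples.

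The root comparison asks how root transcripts differ under cadmium. At5g24420 (c48425.graph_c0), a probable 6-phosphogluconolactonase of the pentose phosphate pathway, fell from 122.5 ± 17.9 to 3.75 ± 0.829 FPKM, a log2 fold change of -5.06 (adjusted p = 7.56e-22). Pathogenesis-related protein 1, At2g14610 (c40703.graph_c0), fell from 750.0 ± 19.4 to 63.5 ± 12.8 FPKM with a log2 fold change of -3.56. The protease inhibitor WSCP (c47610.graph_c0) fell from 762.1 ± 36.8 to 104.7 ± 5.30 FPKM, and the berberine bridge enzyme-like protein At4g20820 (c57972.graph_c1) from 154.4 ± 16.2 to 21.8 ± 0.66 FPKM. AMY1, an alpha-amylase, fell from 36.1 ± 3.13 to 3.24 ± 0.392 FPKM, and the nucleolin gene NUCL2 from 92.05 ± 6.52 to 12.9 ± 2.97 FPKM. Among the largest rises, XTH25 (c59711.graph_c1), which codes for an enzyme that remodels cell-wall xyloglucan, went from 9.29 ± 1.30 to 64.3 ± 7.49 FPKM with a log2 fold change of 2.81 (adjusted p = 2.09e-15). The nitrate transporter gene NPF7.2 (c23375.graph_c0) rose from 13.4 ± 1.23 to 69.6 ± 19.4 FPKM with a log2 fold change of 2.47 (adjusted p = 6.32e-09).

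The other genes with large rises in the root started low. They were the defensin-like At1g34047, the transposon-derived RE1, COR15B, ASHH2, AZI1, At1g30560 and an alanine and glycine-rich protein, with log2 fold changes from 2.11 to 3.27. A cell wall / vacuolar inhibitor of fructosidase 1-like gene rose by 3.09 on the log2 scale (adjusted p = 0.00672), which became 0.0549 without cadmium root library 1. The other large falls were F6'H2 at -4.58, ADS3.2 at -3.92, KTI1 at -3.67 and MLP329 at -3.05 on the log2 scale. With edgeR, 5961 of 27114 tested genes passed an adjusted p of 0.05, 2874 of them higher and 3087 lower in cadmium roots, and 1452 changed at least 2-fold. Of the 5961, 767 were transcripts classed as oomycete and 50 came from the other organisms rather than from the plant. A fit of plant and unmatched transcripts alone called 5183 of 22136, 2495 higher and 2688 lower. With all transcripts, leaving out 1 library gave 4661 to 5473 genes, DESeq2 gave 4691 and limma on log2(FPKM + 1) gave 4157. A fit of all 12 libraries, in which the leaf spread enters the variance, called 791, all of them among the 5961. Of the genes named so far it missed At5g24420 (adjusted p = 0.131), At2g14610 (0.0643), WSCP (0.277), NUCL2 (0.0949), KTI1 (0.522), MLP329 (0.084), COR15B (0.175) and the fructosidase inhibitor gene (0.07). For every gene said here to have risen or fallen in the root, the 3 cadmium values lay on one side of the 3 control values, which chance gives for 10% of genes. The rule for the largest rises and falls required this, and the other genes had already been called. It is therefore a description and no further support.

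**Figure D1:**
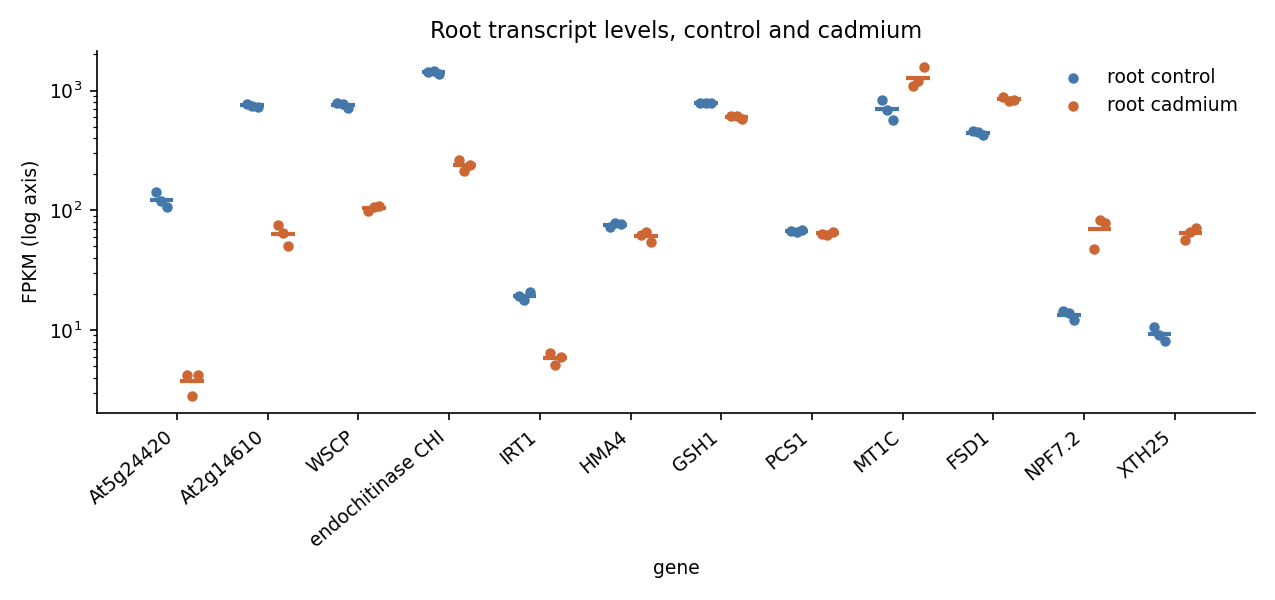
FPKM on a log axis of 12 genes in the 3 control and the 3 cadmium root libraries, 1 point per library with a line at the group mean. At5g24420 fell from 122.5 to 3.75 FPKM and XTH25 rose from 9.29 to 64.3 FPKM, while PCS1 stayed at 67.3 and 64.1 FPKM and did not pass.

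Genes for binding, moving and taking up metals went both ways in the root. The metallothionein gene MT1C (c52430.graph_c0), coding for a cysteine-rich metal-binding protein, rose from 696.7 ± 135 to 1283 ± 251 FPKM with a log2 fold change of 0.90 (adjusted p = 7.75e-08). GSH1 (c60760.graph_c0), which makes the first step of glutathione synthesis, fell from 784.8 ± 4.38 to 601.4 ± 16.8 FPKM with a log2 fold change of -0.41 (adjusted p = 1.91e-08). PCS1, the phytochelatin synthase gene, was at 67.3 ± 1.05 and 64.1 ± 1.98 FPKM and did not pass (adjusted p = 0.311). IRT1 (c60905.graph_c0), the main iron uptake transporter, which also carries cadmium, fell from 19.3 ± 1.49 to 5.80 ± 0.667 FPKM with a log2 fold change of -1.71 (adjusted p = 1.42e-11). The coumarin-synthesis genes F6'H1 and CYP82C4, picked after their values were seen, had 113 and 144 counts over the control roots and none in cadmium roots, at least 37.1-fold and 47.2-fold lower against a floor of 3 counts over the group. HMA4, a zinc and cadmium export pump, fell from 75.6 ± 3.15 to 60.7 ± 5.56 FPKM (adjusted p = 3.15e-05, and 0.0926 by limma without a variance trend). HMA3 fell from 7.36 ± 1.31 to 5.66 ± 0.262 FPKM (adjusted p = 0.0172), but this became 0.0568, 0.148 and 0.0645 without control root library 1, control root library 3 and cadmium root library 3, and 0.193 by limma on log2(FPKM + 1). NRAMP3, at 22.2 ± 1.91 and 19.96 ± 1.84 FPKM, and APR2, at 99.3 ± 3.53 and 97.2 ± 2.93 FPKM, did not pass, and no gene carried the symbol MT2A. A type 2 metallothionein-like gene, MT2-22 (c53975.graph_c0), was at 792.37 ± 55.12 and 1101.11 ± 205.24 FPKM in control and cadmium roots. It passed in edgeR but not in DESeq2 (0.126), limma without a variance trend (0.11) or the fit of all 12 libraries (0.331). YSL3 rose from 51.8 ± 0.624 to 82.8 ± 5.64 FPKM, the ferritin gene FER3 from 62.7 ± 2.22 to 95.7 ± 2.65 FPKM and the sulfate transporter gene SULTR3;1 from 31.3 ± 1.22 to 60.01 ± 1.40 FPKM, while the vacuolar iron transporter homolog At3g25190 fell from 12.7 ± 1.11 to 5.99 ± 0.667 FPKM. The fit of all 12 libraries missed MT1C (adjusted p = 0.22), GSH1 (0.0536), HMA4 (0.246), HMA3 (0.802), FER3 (0.306) and At3g25190 (0.124).

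Of the 46 photosynthesis genes tested in the root, 32 were lower under cadmium. LHCB1.3 (c59937.graph_c0), a light-harvesting protein gene, fell from 130.6 ± 12.9 to 35.7 ± 15.8 FPKM with a log2 fold change of -1.84 (adjusted p = 1.68e-10). PSBO1 fell from 42.0 ± 3.81 to 11.0 ± 1.47 FPKM, the Rubisco small subunit gene RBCS from 84.8 ± 6.11 to 26.8 ± 2.81 FPKM and GAPA2 from 24.4 ± 2.48 to 7.40 ± 0.887 FPKM. The chlorophyll synthesis genes PORC and HEMA1 fell from 19.9 ± 0.675 to 5.99 ± 0.3 FPKM and from 170.9 ± 4.47 to 116.0 ± 6.46 FPKM. RFNR2, the root isozyme of ferredoxin reductase, rose from 208.6 ± 10.6 to 248.4 ± 8.02 FPKM, and the plastid gene psaB, at 188.6 and 186.4 FPKM, did not pass (adjusted p = 0.523). Neither did some nuclear genes, such as LHCB2.4 (log2 fold change -0.10) and LFNR2 (-0.10). By camera, 25 of 35 light-reaction genes were lower and 1 higher (median -1.62, or -1.60 with the gene at the floor set to its bound; adjusted p = 4.4e-26), 7 of 11 Calvin cycle genes were lower (median -1.44, adjusted p = 1.7e-09), and chlorophyll synthesis had 7 of 14 lower and 1 higher (median -0.31, adjusted p = 9.3e-04). With an estimated correlation between genes these became adjusted p = 0.0986, 0.0986 and 0.171. The chlorophyll synthesis list was not called by limma on log2(FPKM + 1) (adjusted p = 0.12), and the fit of all 12 libraries missed HEMA1 (0.372) and RFNR2 (0.54, and 0.0937 by limma without a variance trend).

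**Figure D2:**
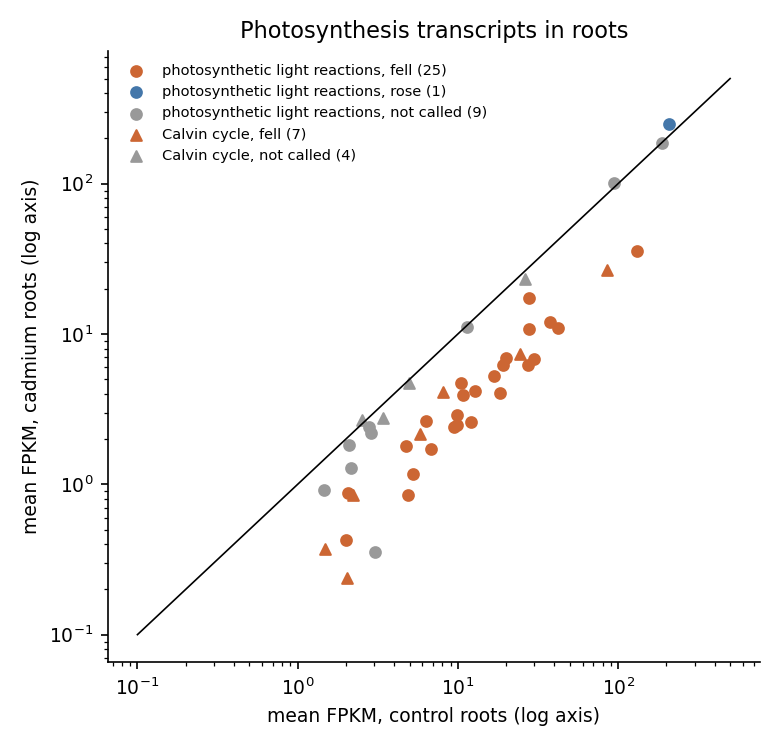
Mean FPKM in cadmium roots against control roots, both on log axes, for the 46 tested members of the light-reaction and Calvin cycle lists, with a line at equality. The 32 members that fell lie below the line, and the 1 that rose is RFNR2.

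Among defence, glucosinolate and jasmonate genes, more were called lower than higher in cadmium roots. An endochitinase gene with the symbol CHI (c48902.graph_c0) fell from 1425 ± 39.1 to 238.5 ± 25.1 FPKM, a log2 fold change of -2.54 (adjusted p = 2.04e-22). The PRB1 gene c42225.graph_c0 fell from 2531 ± 88.2 to 1573 ± 121 FPKM and its near copy c40915.graph_c0 from 2447 ± 59.0 to 1528 ± 176 FPKM, whereas the PR-1 gene c45673.graph_c0 rose from 61.4 ± 7.11 to 120.6 ± 6.69 FPKM. The myrosinase gene MB3, for the enzyme that breaks down glucosinolates, fell from 746.6 ± 11.0 to 588.6 ± 32.7 FPKM. IGMT4 (c62706.graph_c0) fell from 594.1 ± 21.4 to 459.9 ± 15.3 FPKM, and IGMT1 rose from 70.7 ± 3.29 to 105.8 ± 7.73 FPKM. The glutathione transferase genes GSTF3 and GSTF9 fell from 3057 ± 125 to 1652 ± 121 FPKM and from 1740 ± 67.9 to 1303 ± 25.96 FPKM. WRKY33 fell from 337.8 ± 13.4 to 251.5 ± 3.10 FPKM, and TIFY10A, a repressor of jasmonate signalling, from 733.0 ± 18.9 to 544.1 ± 19.5 FPKM. Defence proteins had 29 of 74 lower and 10 higher (median -0.21, adjusted p = 9.2e-12), glucosinolate genes 22 of 51 lower and 5 higher (median -0.36, adjusted p = 1.4e-04), and jasmonate genes 12 of 33 lower and 1 higher (median -0.20, adjusted p = 4.6e-04). With an estimated correlation these became adjusted p = 0.0986, 0.296 and 0.171, and in the fit of all 12 libraries 0.172, 0.129 and 0.129. That fit also missed all genes named in this paragraph except IGMT1 and the PRB1 gene c42225.graph_c0, with adjusted p from 0.0745 for CHI to 0.783 for IGMT4.

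The remaining called lists in the root were smaller shifts. In the abscisic acid list, the dehydrin gene ERD14, whose product protects cells that lose water, rose from 332.9 ± 29.5 to 615.9 ± 47.3 FPKM and ERD10 from 368.5 ± 14.4 to 557.1 ± 34.7 FPKM, while CYP707A3 fell from 511.4 ± 22.4 to 393.3 ± 5.77 FPKM. HIRD11, also a dehydrin gene, fell by 0.19 on the log2 scale (adjusted p = 0.0021), a direction that turned with quantile normalization. That list had 12 of 44 genes higher and 6 lower (median 0.20, adjusted p = 0.00117), and the cell wall list 25 of 111 higher and 7 lower (median 0.10, adjusted p = 0.00117). With an estimated correlation, the adjusted p of these and the 5 other lists of this paragraph lay between 0.171 and 0.346. Cell division had 45 of 154 genes lower and 9 higher (median -0.16, adjusted p = 0.00369). The glutathione transferases had 15 of 53 lower and 5 higher (median -0.06, adjusted p = 4.96e-04), although their mean was 0.01. Phenylpropanoid genes had 18 of 65 lower and 6 higher (median -0.09, adjusted p = 0.0265), and WRKY genes 18 of 74 lower and 7 higher (median -0.10, adjusted p = 0.0329). The flavonoid list had 3 of 13 lower and 2 higher (median -0.10, adjusted p = 0.00503), but its largest fall was the endochitinase CHI, which entered by its symbol and is no flavonoid enzyme, and chalcone synthase CHS rose from 0.793 ± 0.179 to 3.65 ± 0.413 FPKM. The call for phenylpropanoid genes ended without control root library 3 (0.078) and that for WRKY genes without control root library 2 (0.0586), and limma on log2(FPKM + 1) called neither these lists nor the flavonoid and cell wall lists. The fit of all 12 libraries called none of the 7 lists except abscisic acid, and missed CYP707A3 (0.814) and HIRD11 (0.464). HIRD11 was also missed by limma without a variance trend (0.119).

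The other 17 lists did not pass in the root. Metal chelation had 4 genes higher and 4 lower of 13 (adjusted p = 0.547), metal transport 8 and 12 of 62 (0.682), iron deficiency response 2 and 6 of 21 (0.12, and 0.0116 without a filter on low values), ferritin and iron storage 1 and 2 of 8 (0.874), and sulfate uptake 6 and 8 of 44 (0.676). Antioxidant enzymes had 9 higher and 11 lower of 54 (0.874). There FSD1, an iron superoxide dismutase gene, rose from 443.3 ± 17.5 to 845.4 ± 35.4 FPKM and the catalase gene CAT3 fell from 1265 ± 46.1 to 1021 ± 21.9 FPKM. Class III peroxidases had 15 and 16 of 62 (0.676), ethylene genes 29 and 17 of 125 (0.484), heat shock proteins 6 and 7 of 69 (0.875), NAC factors 6 and 12 of 61 (0.275) and aquaporins 5 and 3 of 28 (0.657). Nitrate genes had 12 and 12 of 54 (0.676), with NIR1, a nitrite reductase gene, up from 325.3 ± 4.06 to 487.6 ± 8.56 FPKM. The fit of all 12 libraries missed FSD1 (0.117), CAT3 (0.296) and NIR1 (0.075). Phosphate genes had 10 and 10 of 55 (0.79), cytosolic ribosomal proteins 19 and 10 of 209 (0.676), leaf senescence 5 and 1 of 18 (0.118, and 0.0484 without cadmium root library 1), root tissue markers 0 and 3 of 11 (0.275), and flower, pollen and seed markers 0 and 0 of 6 (0.874). Median and test differed in sign for antioxidant enzymes (-0.06, test higher), ribosomal proteins (-0.004, test higher), metal chelation (0.005, test lower) and ferritins (0.002, test lower), and mean and median did for metal transport, aquaporins and leaf senescence. Over the 30 root lists, 569 memberships passed over all genes tested and 596 when adjusted over the list alone.

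**Figure D3:**
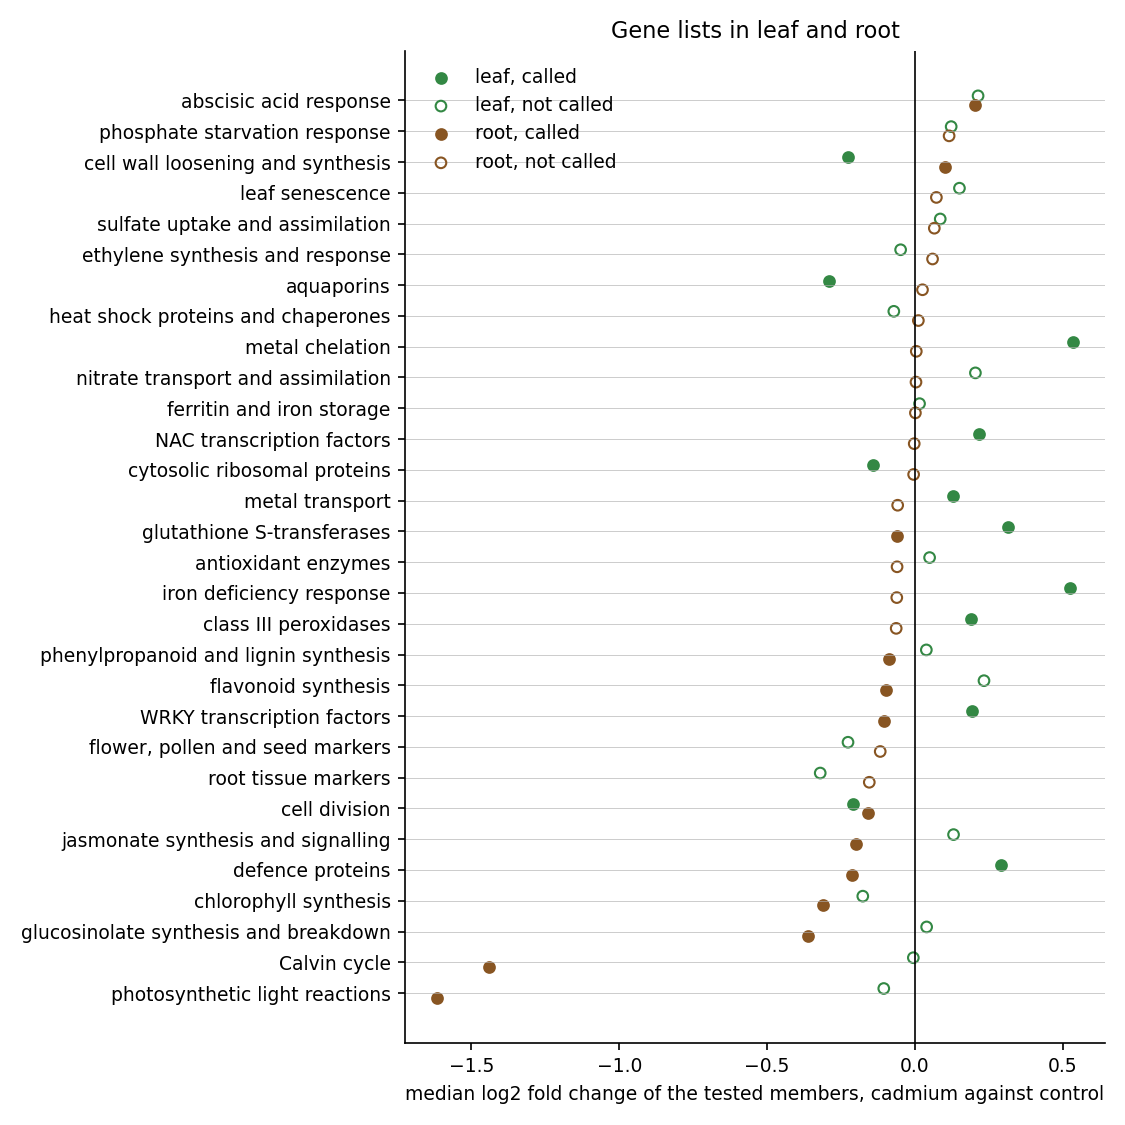
Median log2 fold change of the tested members of each of the 30 gene lists, cadmium against control, in leaf (green) and root (brown), with filled points for lists called by camera at the preset correlation. The light-reaction and Calvin cycle lists lie at -1.62 and -1.44 in the root and at -0.11 and -0.01 in the leaf.

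In leaves, the comparison asks how leaf transcripts differ under cadmium, and no gene passed in edgeR. The genes with the lowest p are named instead, each with adjusted p = 0.701. LTI65 (c49835.graph_c0), an abscisic acid-responsive gene, was at 10.4 ± 3.42 FPKM in control and 37.7 ± 11.7 FPKM in cadmium leaves, and NAC072 (c56477.graph_c0), a dehydration-responsive transcription factor gene, at 19.1 ± 1.23 and 45.8 ± 20.2 FPKM. The lipid-transfer protein gene LTP4 was at 64.3 ± 9.78 and 342.5 ± 241 FPKM, and ADF2 at 11.1 ± 0.731 and 20.2 ± 1.16 FPKM. The cytokinin receptor gene AHK4 (c58284.graph_c0) was at 6.33 ± 1.92 and 2.25 ± 0.286 FPKM, XTH18 at 29.9 ± 15.5 and 9.57 ± 0.305 FPKM, and the dehydrin gene ERD10 at 155.9 ± 16.7 and 87.9 ± 6.21 FPKM. Of the genes chosen in advance, PCS1 was at 31.4 ± 1.48 and 42.7 ± 7.38 FPKM, GSH1 at 270.2 ± 27.9 and 288.8 ± 46.5 FPKM, HMA4 at 13.3 ± 3.35 and 12.02 ± 0.618 FPKM and APR2 at 354.8 ± 36.2 and 339.9 ± 76.3 FPKM. HMA3, IRT1 and NRAMP3 were at 1.06 ± 0.986 and 2.44 ± 2.25, 1.42 ± 0.814 and 2.35 ± 1.59, and 11.9 ± 1.51 and 11.4 ± 1.05 FPKM, and none of these 7 passed.

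Of 19697 genes tested in the leaf, 0 passed in edgeR and in limma, 1379 had an unadjusted p under 0.05 in edgeR, and DESeq2 called 38, 21 higher and 17 lower. Among those were 15 of the 20 genes named by lowest p, with LTI65, LTP4 and AHK4 at an adjusted p of 4.89e-04. A fit of all 12 libraries called 12 genes, among them AHK4, ADF2, ERD10 and PCR2. In that fit the smaller root spread enters the variance, so its leaf calls may rest on too small a variance. There 3103 leaf genes had an unadjusted p under 0.05, against 1379. A test without a filter on low values called 1, the unmatched transcript c63820.graph_c0. Leaving out each library gave 0 calls throughout, while the genes with an unadjusted p under 0.05 went from 1379 to 777 without cadmium leaf library 1 and to 2175 without cadmium leaf library 2. The libraries of a leaf group differed much more than those of a root group, with a biological coefficient of variation of 29.2% against 6.2%. In simulated data made from the leaf libraries, edgeR found 71.2% of genes changed 4-fold and 17.9% of those changed 2-fold. There the spread of a gene followed from its expression level alone and genes varied independently, so these shares need not hold for the real leaf libraries. The deposited table marks 312 leaf genes as changed by DESeq2, at a p of 0.01 and a fold change of 1.5. The calls here used an adjusted p of 0.05 without a fold threshold, so the counts are not directly comparable. Of the 312, 307 were tested here. All 307 had an unadjusted p under 0.05 and none passed. In the root it marks 1834 genes, and all 1761 tested here were called in the same direction.

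Leaf genes for metal binding and uptake lay higher under cadmium as lists, although no single gene passed and single libraries differed. Metal chelation had 11 of 13 genes higher (median 0.54, adjusted p = 3.4e-04), iron deficiency response 12 of 14 (median 0.53, adjusted p = 0.0163), metal transport 43 of 58 (median 0.13, adjusted p = 0.00159) and glutathione transferases 26 of 36 (median 0.32, adjusted p = 0.00108). None of these calls, nor the 8 that follow, held with an estimated correlation, where the adjusted p lay between 0.443 and 0.78. NAC factors (median 0.22, adjusted p = 0.00159), WRKY factors (0.19, 0.00948), class III peroxidases (0.19, 0.00919) and defence proteins (0.29, 0.0163) also lay higher. Cell division genes lay lower, 116 of 146 (median -0.21, adjusted p = 2.2e-04), as did cytosolic ribosomal proteins (-0.14, 0.00108), cell wall genes (-0.23, 0.00108) and aquaporins (-0.29, 0.0081). Other splits of the 6 leaf libraries into 3 and 3 called up to 15 lists, against 12 for the real one. As the median over a list of log2 levels less each gene's mean over the 6 libraries, metal chelation was at -0.29, -0.04 and -0.28 in control leaf libraries 1 to 3 and at 0.56, -0.17 and 0.18 in cadmium leaf libraries 1 to 3. Glutathione transferases were at -0.2, -0.01 and -0.12 and at 0.32, -0.01 and 0.13. Cadmium leaf library 2 thus lay among the controls for metal chelation and level with control leaf library 2 for the transferases, whose call ended without a filter on low values (0.0708). Single libraries decided several of the other calls. The iron deficiency list was at 0.755 without cadmium leaf library 2, 0.209 without control leaf library 3 and 0.0823 without control leaf library 1. Cell division was at 0.297 without control leaf library 1, and the ribosomal list then had a median of 0.02 and turned higher (0.634). NAC, WRKY and aquaporin genes were at 0.235, 0.245 and 0.182 without cadmium leaf library 1. WRKY genes were at 0.0578 without control leaf library 3, and peroxidases at 0.0546 without cadmium leaf library 3. Defence proteins were at 0.0788, 0.567, 0.116 and 0.0831 without control leaf libraries 2 and 3 and cadmium leaf libraries 1 and 3.

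The other 18 leaf lists did not pass with all libraries. Photosynthetic light reactions had 37 of 47 genes lower (median -0.11, adjusted p = 0.297) and chlorophyll synthesis 11 of 14 (median -0.18, adjusted p = 0.164). Without control leaf library 1 both passed, at 2.2e-05 and 0.00632, and without cadmium leaf library 2 at 0.00871 and 0.0131. Abscisic acid genes had a median of 0.21 (adjusted p = 0.0564), and passed without control leaf library 2 (0.0159) or 3 (0.0422) and by limma on log2(FPKM + 1) (0.0393). Sulfate genes (0.09, 0.118) passed without control leaf library 2 (0.0159) or cadmium leaf library 3 (0.0125). Nitrate genes (0.21, 0.14) and jasmonate genes (0.13, 0.181) passed without control leaf library 2 (0.0256 and 0.0383), and flavonoid genes (0.23, 0.297) without cadmium leaf library 1 (0.0347). The median and adjusted p were 0.12 and 0.14 for phosphate genes, 0.05 and 0.507 for antioxidant enzymes, 0.04 and 0.651 for phenylpropanoid genes, 0.04 and 0.507 for glucosinolate genes and 0.15 and 0.59 for leaf senescence. They were -0.05 and 0.971 for ethylene genes, -0.07 and 0.442 for heat shock proteins, -0.01 and 0.971 for the Calvin cycle, -0.32 and 0.148 for root tissue markers and -0.23 and 0.627 for flower, pollen and seed markers. Ferritins had a median of 0.02 with a test that pointed lower (adjusted p = 0.686). Over the leaf lists 0 memberships passed over all genes tested and 1 when adjusted over the list alone.

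Whether a gene responded differently in the tissues was tested as root change minus leaf change. NUCL1 (c49219.graph_c0) went from 13.6 ± 1.92 to 1.82 ± 0.555 FPKM in the root and from 2.69 ± 0.730 to 5.37 ± 2.51 FPKM in the leaf, a difference of -3.74 on the log2 scale (adjusted p = 0.00165). At4g20820 (c57972.graph_c1) fell in the root while the leaf stood at 65.0 ± 8.16 and 64.1 ± 8.53 FPKM, a difference of -3.13 (adjusted p = 1.86e-04). The aspartyl protease gene At5g10770 (c63660.graph_c0) was at 11.3 ± 1.00 and 1.49 ± 0.450 FPKM in the root and at 7.01 ± 0.467 and 18.3 ± 9.76 FPKM in the leaf (-4.35, adjusted p = 0.0058). GSTF14 fell in the root from 328.9 ± 29.6 to 43.8 ± 3.54 FPKM and stood at 5.25 ± 1.48 and 10.4 ± 6.496 FPKM in the leaf (-3.92, adjusted p = 0.00982). AZI1 (c23553.graph_c0) rose in the root from 1.62 ± 0.235 to 6.96 ± 1.77 FPKM and stood at 699.2 ± 36.2 and 405.2 ± 128 FPKM in the leaf (2.89, adjusted p = 0.00567). The cell-wall genes XTH8 and XTH16, the MADS-box gene AGL6 and RE1 differed by 2.58, 1.96, 2.21 and 1.99, and At3g55800, a Calvin cycle phosphatase gene, by -3.005. At3g55800 was low in the root, at 2.02 ± 0.43 and 0.24 ± 0.08 FPKM, against 1094.1 ± 210.5 FPKM in control leaves. Its root loss was 0.163% of that leaf level, which a trace of leaf RNA in control roots could cover. In all, 170 of 17631 genes passed, 73 with a higher and 97 with a lower root change. This count moved to 1055 without cadmium leaf library 2 and to between 21 and 36 without any 1 of the 6 root libraries. Without control root library 1, 2 or 3 it was 26, 29 and 26, and without cadmium root library 1, 2 or 3 it was 21, 36 and 29. Leaf and root share 1 variance per gene in this fit, so leaving out a library also changes the weight of the wider leaf spread. These counts therefore do not show what the library left out contributes. DESeq2 called 779 and limma on log2(FPKM + 1) called 104. NUCL1, At4g20820, At5g10770 and AZI1 passed without each library, and GSTF14 missed without cadmium root library 1 (0.0506). XTH8, XTH16 and AGL6 missed without each root library, RE1 (up to 0.0661) without control root library 1 or 2 or cadmium root library 1 or 3, and At3g55800 without cadmium root library 1 (0.0566) or 3 (0.0508). With the replicate number as a block, 78 genes passed, and XTH8 (0.115), XTH16 (0.0766), AGL6 (0.0643) and RE1 (0.0572) were not among them. RE1 was also missed by limma on log2(FPKM + 1) (0.06), XTH8 (0.0654), RE1 (0.0727) and At3g55800 (0.0574) by limma without a variance trend, and XTH8 and GSTF14 (0.0504 each) by limma on log2(FPKM + 0.1). For the lists, the difference between tissues was not tested.

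**Figure D4:**
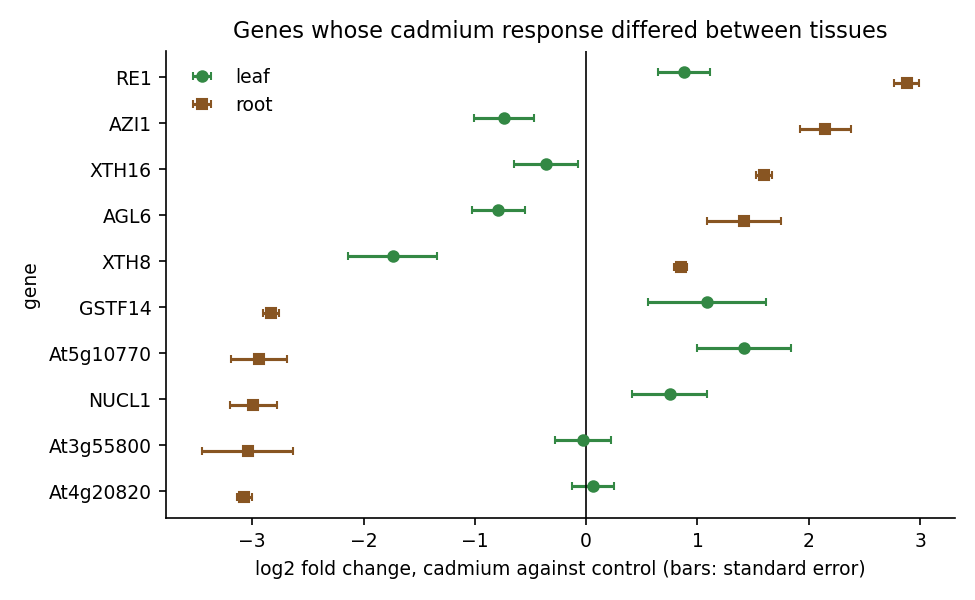
Log2 fold change under cadmium in leaf (circles) and root (squares), with standard errors, for the 10 named genes whose response differed between the tissues. XTH8 lies at -1.74 in the leaf and 0.85 in the root, and At4g20820 at 0.06 and -3.07.

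Leaf and root changes correlated weakly across genes. Of the genes called in the root and tested in both tissues, such as GSTF14, XTH16 and At4g20820, 4185 in all, 51.7% had a leaf change of the same sign, against 52.8% of all 17631 genes tested in both. Pearson's r across genes was 0.07 and Spearman's rho 0.06, and genes are not independent replicates. Without control leaf library 1 or 3 or cadmium leaf library 1, r became -0.01, 0.13 and 0.14. No gene was called in both tissues by edgeR, and 19 were by DESeq2. Of these, 5 were higher in both tissues against 1.6 expected by chance (Fisher's exact p = 0.0175), 7 were lower in both against 1.54 expected (Fisher's exact p = 3.9e-04), and 7 went in opposite directions against 3.14 expected.

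Control roots and control leaves differed in most genes, which describes the tissues. The peroxidase gene PER45 was at 454.2 ± 6.39 FPKM in control roots and had no count in the 3 control leaf libraries, at least 6340-fold higher against a floor of 3 counts over the group. The peroxidase genes HRPN and PER15 were at least 5107-fold and 4961-fold higher in roots, ESM1 at least 4301-fold and the germin-like gene At3g05950 at least 3132-fold. LHCA6, a photosystem I antenna gene, was at 146.9 ± 29.5 FPKM in leaves and had no count in control roots, at least 1824-fold lower there, and CRR7 was at least 760-fold lower. BCA1, a carbonic anhydrase gene, was at 3603 ± 1325 FPKM in leaves and 0.79 ± 0.352 FPKM in roots. With edgeR, 17284 of 25468 genes passed, 10905 higher in root and 6379 higher in leaf. The split depended on the method, with 12979 and 5046 by limma on log2(FPKM + 1) and 8790 and 7484 by quantile normalization. It also depended on the transcripts tested. All 3456 tested transcripts of the oomycete class were called higher in root, a direction set by the class, which holds only transcripts with under 2% of their counts in the leaf. With plant and unmatched transcripts only, edgeR called 7170 genes higher in root and 6219 higher in leaf, with a median log2 fold change of 0.09. The median log2 fold change of all tested genes was 0.30 in edgeR and 0.28 with median-ratio scaling, against 0.52 by limma on log2(FPKM + 1) and 0.09 by the same test after quantile normalization. Single changes are therefore relative to the test, the scaling and the transcripts used. Without 1 library the count lay between 15727 and 18338.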

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

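The tests of counting noise, of the most abundant transcripts, of transcript length and of plants that differ in their genes were chosen only after the spread of the leaf libraries was seen. The regroupings were set before. The response to cadmium differed between root and leaf for 170 genes by an interaction test, which is why these results are given here. The named differences of root minus leaf change were 2.89 for AZI1, 2.58 for XTH8, 2.21 for AGL6, 1.99 for RE1 and 1.96 for XTH16. They were -4.35 for At5g10770, -3.92 for GSTF14, -3.74 for NUCL1, -3.13 for At4g20820 and -3.005 for At3g55800. At3g55800 stood at only 2.02 and 0.24 FPKM in control and cadmium roots, a loss that a trace of leaf RNA could cover.

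Chance was not excluded for this count. Of 100 regroupings of treatment within tissue, drawn from 200, 5 including the real one gave at least 170 genes, with 611 as the highest other. One, with 215 genes, kept the real groups of both tissues and only exchanged the root labels. All 5 kept the 3 libraries of each root group together, as 11 of the 100 did, and regroupings that parted them called at most 17 genes. Those 5 therefore still held the difference between the root groups, so these regroupings could not decide whether chance gives 170 genes. Control leaf libraries 2 and 3 grouped with cadmium leaf library 2 gave 442 and 611 genes, more than the real leaf groups, which points to a structure among the leaf libraries. Without cadmium leaf library 2 the count was 1055, and without 1 root library it lay between 21 and 36.

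The leaf libraries of a group lay far apart. Counting noise was argued against, since the lowest chi-square per degree of freedom between leaf libraries of a group was 26.45 and the highest 134.41, against 2.49 to 5.01 in the root at similar depth. A few abundant transcripts were argued against as the whole cause, since without the 100 most abundant of each tissue these values were 23.93 to 75.58 in the leaf and 2.38 to 4.25 in the root, although the leaf values fell. The test set before, the coefficient of variation without them, could not decide this, because they are too few of the 19697 genes. Transcript length was argued against too, as it accounted for at most 2.19% of a leaf library's variance. A candidate explanation is that leaf libraries came from plants that differ in the genes they carry or express. Each pair of leaf libraries of a group had at least 13 transcripts with 50 or more counts in one library and none in the other, up to 54, and each root pair had 0. So few transcripts beside the 19697 genes tested do not show what made the spread over all genes. Whole lists moved too, with medians of -0.36, 0.19 and 0.28 for light reactions in control leaf libraries 1 to 3. For cytosolic ribosomal proteins these were 0.36, -0.02 and -0.15. The cause of these shifts was not tested. If root libraries came from shared material, which the labels do not say, root p-values may not cover the spread between plants.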

How the results depend on the processing

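The tests with DESeq2, plant transcripts only, lists with other organisms kept and voom weights were chosen after seeing the data. So was the use of edgeR in place of the planned limma on log2(FPKM + 1), which is given as an alternative. Leaf calls went from 0 to 1 without a filter, 12 with all 12 libraries in the fit and 38 with DESeq2. Root calls went from 5961 to 3869 with limma on log2(FPKM + 0.1), 3044 without the variance trend and 791 with all 12 libraries. Calls for the difference between tissues went from 170 to 99 and 103 with limma on log2(FPKM + 0.1) and log2(FPKM + 0.5), 104 on log2(FPKM + 1), 77 without the trend, 1721 without a filter, 779 with DESeq2 and 337 with voom weights per tissue. Root against leaf went from 17284 to 27688 without a filter and 11168 at an FPKM of at least 5, where more and fewer genes were tested. Genes shared by leaf and root went from 0 to 1 without a filter, 4 with all 12 libraries and 19 with DESeq2. Except for those filters, the cause was not tested.

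With the replicate number as a replicate block the counts were 0 in the leaf, 5649 in the root, 78 for the difference between tissues and 15950 for root against leaf. Libraries of the same number did not vary together, with correlations from -0.056 to 0.067. Leaving out 1 library gave 0 in the leaf, 4661 to 5473 in the root, 21 to 1055 for the difference and 15727 to 18338 for root against leaf.

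Across the alternatives, leaf lists kept their direction and their side of the threshold in 523 of 568 cases, with 15 gaining and 29 losing a call. Root lists did so in 510 of 567, with 2 gaining and 55 losing a call. Named genes did so in 488 of 510 in the leaf, where 22 gained a call, 1942 of 2354 in the root, 202 of 237 for the difference and 180 of 180 for root against leaf. In the root 411 and for the difference 35 lost theirs. The cytosolic ribosomal proteins in the leaf reversed without control leaf library 1 (median 0.0163, with medians from -0.2418 to 0.0163 over the 6 libraries left out), and HIRD11 in the root reversed with quantile normalization (0.05). The cause was not tested. In the simulated data of these depths, with the spread set by expression level alone, edgeR found 17.9% of 2-fold changes in the leaf and 74.6% in the root. Depth was not varied.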

Other observations

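The tests of leaf RNA in roots, of the source and amount of oomycete transcripts, and of transcripts missing under one treatment were chosen only after the results were seen. The splits and the test of single libraries were set before. A split of 6 libraries into 3 and 3 has 10 forms, too few for a share under 0.05. As many genes as the real 0 were called by 10 of 10 splits in the leaf, where the highest other was 4. Any split calls at least 0 genes, so this outcome was certain and says nothing about the leaf groups. In the root 1 of 10 splits, the real one with 5961, called as many (highest other 0), and for root against leaf 1 of 10, the real one with 17284 (highest other 0). As many lists as the real 12 were called by 3 of 10 splits in the leaf, with 15 as the highest other, and as the real 13 by 1 of 10 in the root, with 7 as the highest other. For the correlation of leaf and root changes, 25 of 100 combinations of splits lay as far from 0 as the real 0.07, up to -0.22, so chance was not excluded.

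Transcripts matched to oomycetes held 3.53 ± 0.145% of counts in control roots, 3.48 ± 0.0403% in cadmium roots, 0.655 ± 0.0489% in control leaves and 0.63 ± 0.0475% in cadmium leaves (n = 3). Those with under 2% of their counts in the leaf, the class used here, held 2.65 ± 0.133% in control and 2.57 ± 0.0537% in cadmium roots (exact permutation p = 0.4). Plant transcripts matched to oomycete proteins were argued against as the source of most of them, but not of those with leaf counts, since 98.9% of 24781 transcripts annotated to oomycetes had no count in any leaf library, against 17.3% of those annotated to land plants. Pythium gave 44.4% of the class and Phytophthora 32.6%. A difference in the amount of oomycete RNA was argued against as the whole cause of the calls, since scaling to oomycete counts alone gave 773 called transcripts of 4805, where the fit of all transcripts gave 767. The directions did depend on the scaling, with 299 higher and 468 lower in the fit of all transcripts and 385 and 388 when centred on the oomycete counts. Without 1 library the count lay between 590 and 682. Of 10 splits, 1, the real one, called as many as 773 (highest other 0). Cytosolic ribosomal proteins had 62 of 192 higher and 11 lower (adjusted p = 1.9e-04), heat shock proteins 9 and 1 of 26 (1.9e-04), antioxidant enzymes 6 and 1 of 21 (0.0284) and glutathione transferases 1 and 0 of 8 (0.0206). With an estimated correlation these became 0.369, 0.266, 0.266 and 0.369.

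Photosynthesis transcripts were lower in cadmium roots, 32 of the 46 tested. Leaf RNA in the control root libraries was argued against as the whole cause for the 32 as a set. The leaf share that abundant leaf transcripts allow, 0.173%, covers 30.4% of the level lost at the median, where 0.568% would be needed. Of 96 transcripts above 1000 FPKM in leaves, 19 lay below that need, such as BCA1 at 3603 FPKM in leaves and 0.79 in control roots. The Calvin cycle genes RBCS, RCA, GAPB and At3g55800 lost only 0.105%, 0.1%, 0.132% and 0.163% of their leaf level, under 0.173%. For these, leaf RNA could cover the whole loss and was not argued against. GAPA2 lost 0.504% and the light-reaction gene LHCB1.3 lost 0.581%, above that share. Single libraries were argued against as well, with at least 29 of the 32 still lower without any 1 library. A smaller share of leaf RNA, or a response of the root's own plastids to cadmium, stays open, and the latter was not tested.

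Transcripts present in each control library and absent from each cadmium library, in both tissues, numbered 8, and 0 showed the reverse. In 6 of the 8 the lowest control library had only 1 to 4 counts. Of 200 regroupings of treatment within tissue, 3 including the real one gave as many or more, with 10 as the highest other. That share is under 0.05, but the test was built on the pattern that prompted it. The transcript with the most counts was c63820.graph_c0, with 77, 105 and 27 counts in control leaves and 172, 142 and 130 in control roots, at least 68.5-fold and 145.7-fold lower under cadmium against a floor of 3 counts over the group. It passed in the root (adjusted p = 2.13e-14) and not in the leaf (0.701). Another transcript, c32122.graph_c0, had 3707, 0 and 3997 counts in control leaves and counts in the other 9 libraries. Control and cadmium plants may therefore differ in some genes they carry, as leaf libraries of a group may, where each pair had at least 13 transcripts of 50 or more counts missing from one library. A loss of expression under cadmium was not told apart from this.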
